A study of Mus musculus with 12 samples.

How the data were processed

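Gene expression was measured in 12 cultures of mouse skin-derived precursors (SKPs), dermal cells that grow as floating spheres and behave as precursors of the dermis. The cells came from skin of mice aged 9 months, and the strain is given in the labels as CD57/Bl6. There were 4 groups of 3 samples: uninjured skin with vehicle, wounded skin with vehicle, wounded skin with trimebutine maleate, and wounded skin with alprostadil (prostaglandin E1). Per the labels' protocols, cells were plated at 50000 per ml with FGF2 at 40 ng/ml, EGF at 20 ng/ml and B27 at 2%, secondary spheres were grown for each condition, and cDNA was made from 400 ng of total RNA. Drug doses, the time of treatment, the site of the skin and scan dates are not given in the sources used here. The labels number the samples as biological replicates and the series text speaks of independent isolates, so p-values measure the spread between isolates.

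The RNA was hybridised to mouse whole-transcript arrays from Affymetrix (Mouse Gene, version 2.0 ST). The deposited values are log2 expression values per probe set, made by the authors with RMA and the R package oligo, per the submitters' processing notes; versions and settings are not given in the sources used here. The table holds 41345 probe sets on 12 arrays. Of these, 23521 carry 1 gene symbol, 1814 carry several and 16010 carry none in the platform annotation. Only probe sets with 1 symbol were used, and genes of the others are not analysed here. Array medians lay between 6.57 and 6.74 on the log2 scale, and the lowest belonged to replicate 1 of wound alprostadil, uninjured vehicle and wound trimebutine (6.57, 6.61 and 6.62). The number of arrays limits the precision.

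Where a symbol had more than 1 probe set the brightest was kept, giving 22180 genes. A gene was tested if it lay above the array median on at least 3 of the 12 arrays, which left 13153 genes. Sox2 was not tested for this reason. All 4 groups entered 1 linear model in limma 3.58.1 (R 4.3.3), with moderated variances and no covariate, so that the groups shared 8 residual degrees of freedom per gene. P-values are two-sided and were adjusted by Benjamini-Hochberg over the 13153 genes, with a threshold of 0.05. Levels are log2 means with their SD over 3 arrays, and differences are given with the model's standard error (SE).

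Lists of genes for pathways, matrix, growth, stress and cell types were written before the data were examined, 37 in number. Of the 976 listed entries, 885 matched a gene of the annotation, and the others are not analysed here. The 35 lists with at least 5 tested members were set against all other genes with limma's camera at a preset inter-gene correlation of 0.01. P-values were adjusted over the lists of a comparison. Camera was run again with its estimated correlation. Lists were also tested with fry, a rotation test of whether their own members change, which does not set them against other genes. Where the preset correlation is smaller than the estimated one, as for most lists, its p-values are the more permissive. A list score is the mean of its tested members after centring each gene on the 12 arrays.

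The genes named for each of the first 4 comparisons were taken by a rule set before the data were examined: up to 8 rises and 8 falls that passed the threshold without overlap of the groups, with empty places filled by the smallest p in that direction and reported as not passing, the 3 leading members of each list past the camera threshold, and 10 fixed genes. Predicted genes were left out of the first part; Gm16685, which passed, was named after its values were seen. The genes named for the drug groups against uninjured vehicle, and for all wound groups together against uninjured vehicle, were also chosen after their values were seen.

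The scripts were tested on simulated arrays for the injury comparison (13153 genes, 20 draws, 200 changed genes). Of genes changed by 1, 2 and 3 log2 units, 75.7%, 93.7% and 97.7% were recovered, and 5.1% of the genes called were false. The simulated genes varied independently, which the real ones do not. Alternatives planned before the data were examined were a replicate block, 2 other filters on dim probe sets, the mean of probe sets, all probe sets, cyclic loess, median centring, another variance model, array weights, only the groups compared, other thresholds and leaving out each array. A fit without the 3 arrays of lowest median, the comparison of all wound groups together against uninjured vehicle, array weights on other splits of the arrays, and the resampling of residuals for shared control arrays were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.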

Results

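Expression of 13153 genes was compared in SKP spheres from uninjured skin and from wounded skin given vehicle, trimebutine or alprostadil, with 3 arrays in each of the 4 groups. By the title of the series, the work sought drugs that enhance skin repair through screens on dermal stem cells. Fn1 (fibronectin) was bright in every group, with means of 13.85 to 13.91 log2 units, and Pdgfra, a receptor of dermal fibroblasts, had means of 11.71 to 12.50. Nes (nestin), a marker of SKPs, reached at most 7.12 on the 12 arrays.

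The arrays of a group differed widely. The first 3 principal components carried 43.8%, 23.9% and 11.9% of the variance, and wound vehicle replicates 1 and 2 lay at -34.1 and -38.9 on the first while replicate 3 of that group lay at 13.9. Wound alprostadil replicates 1 and 2 lay at -19.3 and -29.6, and replicate 3 at 15.4. Macrophage genes were high on 1 array, wound alprostadil replicate 1, whose macrophage score was 3.27 against -0.97 to 0.25 on the other 11 arrays. Ctss (cathepsin S) was 12.97 there and at most 8.66 elsewhere, and Csf1r, the receptor of the macrophage growth factor CSF1, was 10.12 and at most 6.95 elsewhere. In the limma F test across the 4 groups 2 genes passed, C1ql1 and Mmp1b, each at an adjusted p of 0.0433. The count was 6 without wound vehicle replicate 3, 3 without wound alprostadil replicate 2, 2 without wound alprostadil replicate 3, 1 without wound vehicle replicate 2 and 0 without any other single array.

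**Figure D1:**
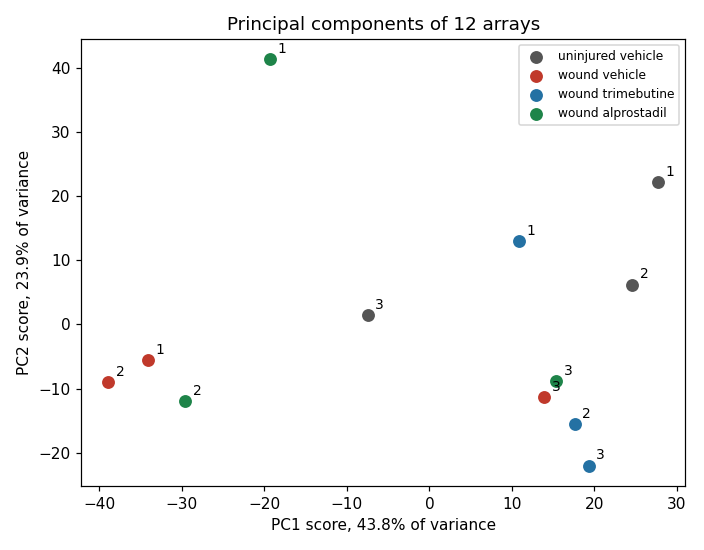
Scores of the 12 arrays on the first 2 principal components of the tested genes (axes: component scores with the percent of variance), coloured by group and numbered by replicate. Wound vehicle replicates 1 and 2 lie at -34.1 and -38.9 on the first component and replicate 3 at 13.9, and wound alprostadil replicate 1 stands highest on the second at 41.3.

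The comparison of wound vehicle with uninjured vehicle asks how spheres from wounded skin differed without a drug. The skin site is not given in the sources used here, so injury and a difference of site cannot be told apart. In limma 6 genes passed, 1 higher and 5 lower in spheres from wounded skin. Nova1, a neuronal splicing regulator, rose by 1.30 ± 0.16 log2 units (SE, n = 3 per group; adjusted p = 0.0338). The falls were in Mmp1b, of the interstitial collagenase family (-1.78 ± 0.18, adjusted p = 0.0228), Itgb8, an integrin that activates latent TGF-beta (-1.79 ± 0.24, adjusted p = 0.0475), Art3 (-1.49 ± 0.19), C1ql1 (-1.09 ± 0.14) and the predicted gene Gm16685 (-2.15 ± 0.29). The 3 arrays of each group did not overlap for any of the 6, an outcome that chance gives for 10% of genes. This adds no support, since the 6 genes were chosen by their differences on these same arrays.

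Several further genes were among the smallest p in their direction without passing. Higher in wound vehicle were Dhrs3, a retinaldehyde reductase, by 1.99 ± 0.28 (adjusted p = 0.0528), Prdm8 by 1.94 ± 0.29, Tbx5, a T-box factor of the forelimb, by 1.77 ± 0.30, and Gata6 by 1.29 ± 0.20. Lower were Bcl11b, a zinc-finger transcription factor (-2.05 ± 0.31, adjusted p = 0.0604), Hoxc9 (-0.98 ± 0.14, adjusted p = 0.0539), Csmd3 (-1.42 ± 0.23) and Itgbl1 (-1.29 ± 0.21).

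By camera with the preset correlation, 14 of 35 lists differed, 12 lower and 2 higher in wound vehicle, and 0 held with an estimated correlation, where the smallest adjusted p was 0.707. Collagen and matrix genes lay lower, with a median of -0.70 and 33 of 36 members below 0 (adjusted p = 5.35e-12, and 0.707 with an estimated correlation). The collagen scores of the wound vehicle arrays were -0.53, -0.76 and 0.10, so replicates 1 and 2 stood lower than replicate 3. No member passed over all genes and 4 passed adjusted over the list alone, and the leading members were Col18a1 (-0.90 ± 0.16), Thbs1 (-1.65 ± 0.31) and Fbln5 (-1.48 ± 0.38). Chemokine and NF-kB target genes had a median of -0.79, with 28 of 30 below 0 and 9 passing adjusted over the list alone (adjusted p = 1.12e-08, and 0.707 with an estimated correlation). Cxcl1, a neutrophil chemokine, differed by -1.98 ± 0.49 and Lcn2 by -1.61 ± 0.30. Interferon response genes had a median of -0.49, with 27 of 28 below 0 and 12 passing adjusted over the list alone (adjusted p = 4.68e-09, and 0.707 with an estimated correlation), led by Psmb9 (-0.83 ± 0.20) and Bst2 (-0.67 ± 0.18).

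Among SKP and dermal papilla genes the median was -0.44 (adjusted p = 2.8e-04, and 0.707 with an estimated correlation), with 6 of 23 passing adjusted over the list alone, and Rspo3, a potentiator of Wnt signalling, differed by -2.17 ± 0.43. Cholesterol synthesis genes were all 19 below 0, with a median of -0.82 (adjusted p = 4.08e-06, and 0.811 with an estimated correlation), and all 32 mitosis genes were below 0, with a median of -0.70 (adjusted p = 1.23e-04, and 0.811 with an estimated correlation). Endoplasmic reticulum stress genes were higher in 20 of 21 cases, with a median of 0.43, and Ddit3 (CHOP) differed by 1.07 ± 0.63 (adjusted p = 0.00253 for the list, and 0.811 with an estimated correlation). That list no longer passed without uninjured vehicle replicate 1 (median 0.23) or wound vehicle replicate 2 (median 0.24). Fgf7 (keratinocyte growth factor, -1.82 ± 0.44), Ccn1 (-2.68 ± 0.66) and Lgr5 (-1.57 ± 0.50) were among the leading members of the growth factor, TGF-beta and Wnt lists, whose medians were -0.28, -0.31 and -0.39 (adjusted p = 0.00893, 0.00364 and 0.00364, and 0.707, 0.811 and 0.707 with an estimated correlation). Without wound vehicle replicate 2 the growth factor list no longer passed (median -0.12). The other lists past the threshold were DNA replication (median -0.28), tenocyte (-0.42), matrix protease (-0.15) and ribosomal protein genes (0.09), at adjusted p of 0.00107, 0.0248, 0.0358 and 0.00415, and each at an adjusted p of 0.811 with an estimated correlation. The DNA replication list was lost without uninjured vehicle replicate 1 (median -0.16), the ribosomal list without wound vehicle replicate 1, the tenocyte list without wound vehicle replicate 1 or 2, and the protease list without uninjured or wound vehicle replicate 1 or 2 or wound alprostadil replicate 1, with medians over all single omissions of 0.06 to 0.15, -0.72 to -0.09 and -0.23 to -0.15 for the last 3. Without uninjured vehicle replicate 1 the medians were -0.35 for mitosis, -0.22 for Wnt and -0.16 for TGF-beta genes. Without uninjured vehicle replicate 2 those of stress and tenocyte genes were 0.25 and -0.22, and without uninjured vehicle replicate 3 that of stress genes was 0.77. Without wound vehicle replicate 1 they were 0.20 for stress, -0.29 for SKP, -0.19 for tenocyte, -0.23 for protease and 0.06 for ribosomal genes. Leaving out wound vehicle replicate 2 gave -0.32 for mitosis, -0.24 for Wnt, -0.16 for DNA replication and -0.09 for tenocyte genes. Without wound vehicle replicate 3 they were -1.21 for mitosis, -0.62 for Wnt, -0.43 for DNA replication, 0.77 for stress, -0.72 for tenocyte, -0.42 for growth factor and 0.15 for ribosomal genes. Hox and positional genes had no common direction (median 0.07, camera adjusted p = 0.844), but fry's test for change in either direction gave an adjusted p of 1.71e-05 and 11 of 25 members passed adjusted over the list alone. Fry does not set a list against other genes, and 13% of all tested genes had an unadjusted p under 0.05 in limma. That fry test passed for 8 lists in all. Those not called by camera were, besides Hox genes, the lists of cell cycle inhibitors and p53 targets (0.00505), cAMP and prostaglandin response (0.0303), endothelial markers (0.0387) and ERK targets (0.0387), and the others were SKP, chemokine and growth factor genes (0.00223, 0.0259 and 0.0405).

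Among the lists past the camera threshold, only chemokine, interferon and collagen genes had scores without overlap of uninjured and wound vehicle arrays. For collagen genes the margin was narrow, with 0.102 on uninjured vehicle replicate 3 and 0.1 on wound vehicle replicate 3. The scores of all other called lists overlapped, those of stress and mitosis genes included. The count of 6 genes became 0 without uninjured vehicle replicate 1 or 2, wound vehicle replicate 1, wound trimebutine replicate 2 or the 3 arrays of lowest median, 1 without wound vehicle replicate 2 or wound alprostadil replicate 1, 3 without wound trimebutine replicate 3, 12 without wound alprostadil replicate 2, 22 without wound alprostadil replicate 3, and 30 without uninjured vehicle replicate 3. At an unadjusted p under 0.05 there were 1709 genes, where 658 would be expected by chance on average. Such counts can vary widely when genes vary together, and another split of these 6 arrays gave 994 genes past the adjusted threshold. The excess alone is therefore not evidence of a broad effect of injury.

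**Figure D2:**
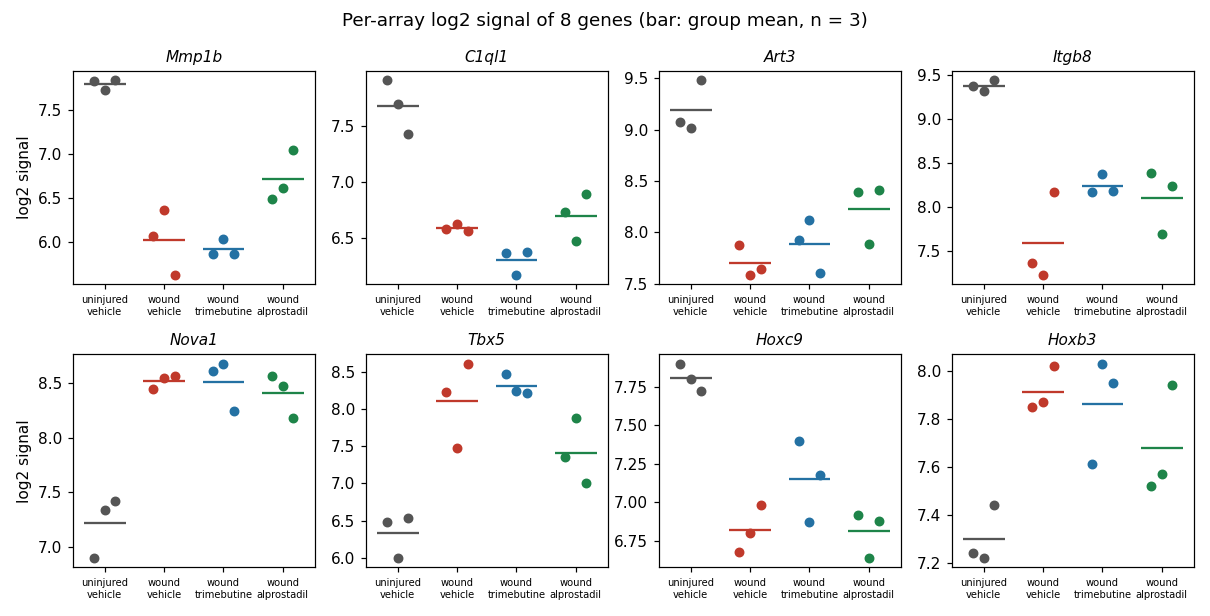
Log2 signal on each array (points; bars are group means, n = 3) of 8 genes in the 4 groups. Mmp1b, C1ql1, Art3, Itgb8 and Hoxc9 are lower, and Nova1, Tbx5 and Hoxb3 higher, on all 9 wound arrays than on the 3 uninjured arrays.

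The comparison of wound trimebutine with wound vehicle asks what the drug changed in spheres from wounds. No gene passed in limma (0 of 13153, smallest adjusted p = 0.528), with 1240 genes at an unadjusted p under 0.05, 839 of them higher with trimebutine. By chance 658 would be expected on average, but such counts can vary widely when genes vary together, so the excess alone is not evidence of a drug effect. Among the values with the smallest p were Qprt, an enzyme of NAD synthesis (0.82 ± 0.15, n = 3 per group), Pcdhb15 (0.68 ± 0.13), Itgbl1 (1.02 ± 0.21) and Esr1, the estrogen receptor (1.06 ± 0.23) on the higher side, and Cd40 (-0.93 ± 0.23), Car9, a carbonic anhydrase induced by hypoxia (-0.51 ± 0.12), and Bcl7a (-0.48 ± 0.11) on the lower. Acta2 (smooth muscle actin) differed by 1.47 ± 0.51, Col1a1 by 0.73 ± 0.31 and Ptger4, a receptor of prostaglandin E, by 1.11 ± 0.45, each with an adjusted p of 0.528. Mki67 differed by 1.34 ± 0.89.

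By camera 12 lists differed, 10 higher and 2 lower with trimebutine, and 0 held with an estimated correlation, where the smallest adjusted p was 0.691 and applied to each list named here. Collagen and matrix genes had a median of 0.73, with 33 of 36 members above 0 and 0 passing (adjusted p = 4.13e-10, and 0.691 with an estimated correlation), led by Eln (elastin, 2.09 ± 0.64), Lox (lysyl oxidase, 1.43 ± 0.49) and Thbs1 (1.10 ± 0.31). All 32 mitosis genes lay above 0 with a median of 0.78 (adjusted p = 4.53e-07, and 0.691 with an estimated correlation), and all 21 endoplasmic reticulum stress genes below 0 with a median of -0.51 (adjusted p = 1.03e-04, and 0.691 with an estimated correlation). Tenocyte genes had a median of 0.41, and Thbs4 differed by 3.47 ± 0.82, the largest difference named in this comparison. Contractile genes, with Mylk (0.67 ± 0.23) and Itga11 (1.48 ± 0.58), had a median of 0.29, and interferon genes one of 0.19 (adjusted p = 0.00644 and 0.00194, and 0.691 for both with an estimated correlation). The remaining 6 lists were TGF-beta, growth factor, DNA replication, papillary and reticular fibroblast, BMP and, on the lower side, ribosomal protein genes, with Ccn2 (1.16 ± 0.44), Angpt1 (1.57 ± 0.50), Mgp (1.63 ± 0.64) and Bmper (2.57 ± 0.92) among their leading members, and each had an adjusted p of 0.691 with an estimated correlation. Each of these 6 was lost without wound vehicle replicate 1 or 2, or both in turn, and 4 of them also without a trimebutine array, BMP genes further without uninjured vehicle replicate 1 or 3 or wound alprostadil replicate 2 (medians 0.12 to 0.46). Single arrays moved several medians. Mitosis genes had a median of 1.33, stress genes one of -0.89 and tenocyte genes one of 0.72 without wound vehicle replicate 3. Without wound vehicle replicate 2 the medians were -0.31 for stress, 0.475 for collagen, 0.21 for tenocyte and 0.13 for contractile genes, and without wound trimebutine replicate 3 that of interferon genes was 0.29. Of the remaining 6 lists, TGF-beta genes (median 0.41) had 0.17 without wound vehicle replicate 1, and BMP genes (0.32) had 0.20 without wound vehicle replicate 1 and 0.12 without wound trimebutine replicate 2. DNA replication genes (0.27) had 0.16 and 0.43 without wound vehicle replicates 2 and 3. Growth factor genes (0.35) had 0.19 and 0.53 without these arrays, and 0.16 and 0.52 without wound trimebutine replicates 1 and 3. Papillary and reticular fibroblast genes (0.40) had 0.25 and 0.70 without wound vehicle replicates 2 and 3, and 0.67 and 0.21 without wound trimebutine replicates 1 and 3. Ribosomal genes (-0.08) had -0.05 and -0.12 without wound vehicle replicates 1 and 3, and -0.05 without wound trimebutine replicate 3. Leaving out wound vehicle replicate 3, whose scores lay apart from replicates 1 and 2 in collagen, mitosis and stress genes, gave 11 genes in place of 0.

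**Figure D3:**
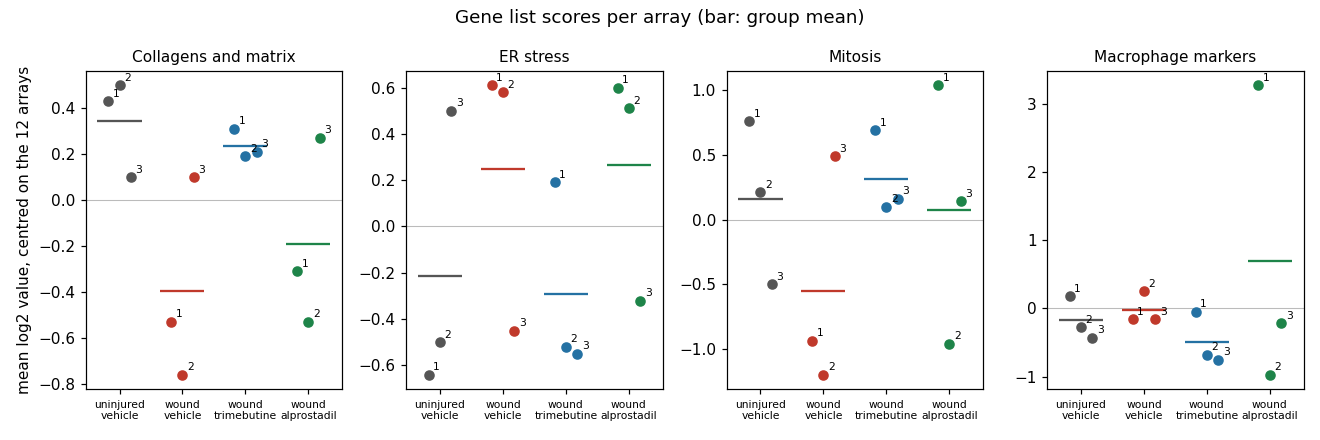
Scores of 4 gene lists on each array (mean of the members after centring each gene; bars are group means, numbers are replicates) in the 4 groups. Collagen scores run from -0.76 in wound vehicle replicate 2 to 0.50 in uninjured vehicle replicate 2, and the macrophage score reaches 3.27 on wound alprostadil replicate 1.

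The comparison of wound alprostadil with wound vehicle asks the same of alprostadil. No gene passed in limma (0 of 13153, smallest adjusted p = 0.998), and 362 genes had an unadjusted p under 0.05, where 658 would be expected by chance. Among the genes with the smallest p were Fam217b (0.51 ± 0.13), Htatsf1 (0.34 ± 0.09), Prom1, a stem cell surface protein (0.71 ± 0.18), and Mmp1b (0.70 ± 0.18) on the higher side, and Prrxl1 (-0.34 ± 0.07) and Fam167b (-0.42 ± 0.09) on the lower. The prostaglandin receptors Ptger4 and Ptgir differed by 0.56 ± 0.45 and -0.17 ± 0.39, Acta2 by 0.29 ± 0.51, Col1a1 by 0.14 ± 0.31 and Mki67 by 0.92 ± 0.89, all with an adjusted p of 0.998. Genes of the cAMP and prostaglandin response list had a median of 0.06 over 27 members (camera adjusted p = 0.921).

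By camera 7 lists differed, 5 higher and 2 lower, and 0 held with an estimated correlation (adjusted p = 0.956 for each). All 32 mitosis genes lay above 0 with a median of 0.58 (adjusted p = 3.45e-05, and 0.956 with an estimated correlation), with Ndc80 at 1.02 ± 0.69. DNA replication genes had a median of 0.22 and histone genes one of 0.40 (adjusted p = 0.0216 for both, and 0.956 with an estimated correlation). Without wound vehicle replicate 1, wound vehicle replicate 2 or wound alprostadil replicate 1 these 3 lists no longer passed, and the mitosis median was 0.37, 0.27 and 0.12, against 1.07 without wound vehicle replicate 3 and 1.08 without wound alprostadil replicate 2. The DNA replication median was 0.13, 0.07 and 0.34 without wound vehicle replicates 1, 2 and 3 and 0.07 without wound alprostadil replicate 1. The histone median was 0.20 without wound vehicle replicate 2, and 0.05 and 0.61 without wound alprostadil replicates 1 and 2. Macrophage genes had a median of 0.70 (adjusted p = 0.0305, and 0.956 with an estimated correlation), and without wound alprostadil replicates 1, 2 and 3 in turn the median was -0.33, 1.57 and 1.32. Chemokine, Hox and skeletal muscle lists were at adjusted p = 0.049 each (0.956 with an estimated correlation), with medians of 0.30, -0.03 and -0.09, and were lost without either uninjured vehicle replicate 1 or 3, among others. The chemokine median was 0.11 without wound vehicle replicate 2 and 0.08, 0.55 and 0.19 without wound alprostadil replicates 1, 2 and 3. The Hox median was -0.10 and 0.02 without wound vehicle replicates 1 and 3 and 0.02, -0.08 and -0.12 without wound alprostadil replicates 1, 2 and 3, and the skeletal muscle median was -0.06 without wound vehicle replicate 3. The macrophage list was also lost without uninjured vehicle replicate 3 (median 0.70), wound vehicle replicate 1 (0.64) or wound vehicle replicate 3 (0.60). Leaving out wound alprostadil replicate 2 gave 1 gene in place of 0.

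Between the drugs, trimebutine minus alprostadil, no gene passed in limma (0 of 13153, smallest adjusted p = 0.752, with 581 genes at an unadjusted p under 0.05). Genes with some of the smallest p were Qprt (0.96 ± 0.15), Spon2 (2.13 ± 0.42) and Aldh1a1, a retinoic acid synthesising enzyme (0.81 ± 0.16), on the side of trimebutine, and Prom1 (-0.92 ± 0.18), Mmp1a (-1.35 ± 0.34) and Tfec (-2.17 ± 0.52), on that of alprostadil. Collagen and matrix genes had a median of 0.43 with 32 of 36 above 0 (adjusted p = 9.17e-08, and 0.704 with an estimated correlation), and contractile genes one of 0.34 (adjusted p = 1.64e-04, and 0.612 with an estimated correlation), with Acta2 at 1.18 ± 0.51. Endoplasmic reticulum stress genes had a median of -0.48 with all 21 below 0 (adjusted p = 1.64e-04, and 0.771 with an estimated correlation). Macrophage genes had a median of -1.35 (adjusted p = 5.38e-04, and 0.771 with an estimated correlation), and without wound alprostadil replicate 1 a median of -0.01. Papillary and reticular fibroblast genes had a median of 0.56 and tenocyte genes one of 0.38, with Thbs4 at 2.77 ± 0.82 (adjusted p = 8.12e-04 and 0.00388, and 0.612 for both with an estimated correlation). Without wound alprostadil replicate 2 the collagen and tenocyte medians were both 0.25, and without wound alprostadil replicate 3 they were 0.73 and 0.57 and the stress median -0.80. Without wound alprostadil replicate 1 the papillary and reticular median was 0.34. Hox and positional genes lay higher with trimebutine, with a median of 0.19 and 19 of 25 above 0 (adjusted p = 0.0012, and 0.612 with an estimated correlation). Their median was 0.105 without wound trimebutine replicate 2 and 0.31 without wound alprostadil replicate 3, and without wound alprostadil replicate 1 the call was lost (0.07). The other lists were chondrocyte (median 0.21), TGF-beta (0.24) and interferon genes (0.14) on the higher side, and neural crest (-0.19) and ribosomal protein genes (-0.06) on the lower. Their adjusted p were 0.0184, 0.0354, 0.0354, 0.046 and 0.00784, and 0.612, 0.771, 0.911, 0.612 and 0.771 with an estimated correlation. The chondrocyte call was lost without wound alprostadil replicate 1 (0.13) and the ribosomal one without wound alprostadil replicate 2 (-0.05), and the ribosomal median was -0.10 and -0.12 without wound trimebutine replicate 1 and wound alprostadil replicate 3. TGF-beta genes no longer passed without wound trimebutine replicate 2 (0.24) or wound alprostadil replicate 1 (0.18) or 2 (0.09), and had 0.42 without wound alprostadil replicate 3. Interferon genes no longer passed without wound trimebutine replicate 1 (0.10) or 2 (0.08) or wound alprostadil replicate 1 (0.004) or 2 (0.06), and had 0.23 and 0.39 without replicate 3 of trimebutine and of alprostadil. Neural crest genes no longer passed without uninjured or wound vehicle replicate 1 (-0.19), wound trimebutine replicate 1 (-0.23) or wound alprostadil replicate 2 (-0.13) or 3 (-0.43), and had -0.295 and -0.10 without wound trimebutine replicates 2 and 3. In all, camera gave 12 lists and the estimated correlation 0. Leaving out wound vehicle replicate 3 or wound alprostadil replicate 2 gave 1 gene in place of 0.

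Against uninjured vehicle, 26 genes passed for wound trimebutine, 13 higher and 13 lower, and 0 for wound alprostadil (limma, smallest adjusted p = 0.111, 954 genes at an unadjusted p under 0.05). In the trimebutine group Mmp1b (-1.88 ± 0.18) and C1ql1 (-1.38 ± 0.14) fell at an adjusted p of 0.00745. Falls at an adjusted p between 0.0285 and 0.0434 were those of Bcl11b (-2.56 ± 0.31), Mmp1a (-2.33 ± 0.34), Zic1 (-1.89 ± 0.28), Col18a1 (-1.14 ± 0.16) and Prom1 (-1.19 ± 0.18). Spon2 (2.71 ± 0.42), Adgrd1 (2.19 ± 0.32), Tbx5 (1.97 ± 0.30), Pde3b (1.94 ± 0.26), Gata6 (1.23 ± 0.20) and Nova1 (1.29 ± 0.16) rose, at an adjusted p between 0.034 and 0.0457. Of the 6 genes that passed for wound vehicle against uninjured vehicle, 5 passed here too, 1 of them higher and 4 lower. Independent lists would share 9.88e-04 and 0.00494. In 100 simulations of unchanged groups 0 genes were shared, but these gave a mean of 0.06 and 0.04 calls, so that they do not measure what the common uninjured arrays add. Part of the overlap may come from those arrays, whose number does not allow a split. All 26 had the same sign in wound alprostadil, which was set against the same uninjured arrays. Sharing alone can give this: in 100 simulations of unchanged groups, 24.3 of the 26 genes of smallest p had the same sign on average (range 21 to 26), and 22.3 (range 1 to 26) when residuals of the real arrays were resampled. The count of 26 became 0 without uninjured vehicle replicate 1, uninjured vehicle replicate 2, wound trimebutine replicate 2 or the 3 arrays of lowest median, and without wound vehicle replicate 1 it became 2, wound trimebutine replicate 3 gave 3, wound alprostadil replicate 1 gave 6, uninjured vehicle replicate 3 gave 10, wound alprostadil replicate 2 gave 12 and wound trimebutine replicate 1 gave 17. Wound alprostadil gave 11 genes without uninjured vehicle replicate 3.

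Across the 13153 genes, which are not independent replicates, the effects of both drugs against wound vehicle correlated at r = 0.507, and unchanged groups sharing the wound vehicle arrays gave a mean of 0.498. Their covariance was 0.0340 against 0.0247 in the simulation, a difference of 0.00933. The injury effect correlated at -0.683 with that of trimebutine and at -0.603 with that of alprostadil, where sharing wound vehicle alone gives -0.500. The covariances were -0.0893 and -0.0453, and differed from the simulated ones by -0.0644 and -0.0205. When residuals of the real arrays were resampled, which keeps the correlation between genes, the covariances of unchanged groups ranged from -0.0178 to 0.103 for the drugs, from -0.114 to 1.76e-04 for injury and trimebutine, and from -0.0941 to 0.0144 for injury and alprostadil (95% ranges, 100 simulations), and all 3 observed values lay inside. With 3 wound vehicle arrays the control could not be split into parts of at least 2 arrays. Without wound alprostadil replicate 3 the correlation of the drugs was 0.023 and that of injury with alprostadil -0.177.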

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

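Tests without the 3 arrays of lowest median signal, the comparison of all wound groups with uninjured vehicle, and the splits with array weights were chosen after the results were seen; the other alternatives were planned. Counts below are of genes at an adjusted p under 0.05 in limma unless another threshold is named, and the cause of a change was not tested except where the setting itself gives it (fewer genes, fewer arrays). Signal over background was not used here, so dim genes are limited by the filter alone.

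Injury (wound vehicle minus uninjured vehicle) gave 6 genes, and trimebutine minus uninjured vehicle 26, all wound groups together 32, and the 4-group test 2. Leaving out 1 array gave 0 to 30 for injury, 0 to 27 for trimebutine minus uninjured vehicle, 0 to 76 for all wound groups, 0 to 6 for the 4-group test, 0 to 11 for trimebutine minus wound vehicle, 0 to 1 for alprostadil minus wound vehicle, 0 to 1 for trimebutine minus alprostadil, and 0 to 11 for alprostadil minus uninjured vehicle. A group left with 2 arrays was assumed to vary like the others. For all wound groups the highest count came without wound alprostadil replicate 3 and the lowest without uninjured vehicle replicate 2. Leaving out 1 array moved the correlation of the drug effects between 0.023 and 0.824, that of injury with trimebutine between -0.822 and -0.558, and that of injury with alprostadil between -0.808 and -0.177.

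The replicate numbers were not taken to pair the samples in the main fit, since the labels name no batch. After removal of group means, 11 of 18 pairs of arrays of different groups with the same number correlated above 0.1 (median 0.22, range -0.64 to 0.62). Of 36 pairs with other numbers 13 did (median -0.11), and 5 of 12 arrays correlated best with their own number, which leaves a shared factor open. With a replicate block injury gave 2 genes (0 higher, 2 lower; 1 and 5 without it), trimebutine minus uninjured vehicle 10 (1 higher, 9 lower; 13 and 13), all wound groups 29 (5 higher, 24 lower; 13 and 19) and the 4-group test 0. A stricter filter on dim probe sets gave 0 for injury, 9 for trimebutine minus uninjured vehicle, 5 for all wound groups and 0 for the 4-group test. Cyclic loess gave 16 for trimebutine minus uninjured vehicle (7 higher, 9 lower) and 1 for the 4-group test. Centring on the median gave 1 for injury (0 higher, 1 lower), 17 for trimebutine minus uninjured vehicle (8 higher, 9 lower) and 1 for the 4-group test. All probe sets gave 0, 3 and 7 for injury, trimebutine minus uninjured vehicle and all wound groups, and 0 for the 4-group test. Only the groups compared gave 0 for injury and 15 for trimebutine minus uninjured vehicle. Without the 3 arrays of lowest median these 4 counts were all 0. An adjusted p under 0.10 gave 21 for injury and 76 for all wound groups. An unadjusted p under 0.05 with at least 1.5-fold gave 691 for injury, 433 for trimebutine and 25 for alprostadil minus wound vehicle, 178 for trimebutine minus alprostadil, 363 and 337 for trimebutine and alprostadil minus uninjured vehicle, 431 for all wound groups and 515 for the 4-group test.

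Array weights gave 4997 genes for injury, 4034 for trimebutine minus wound vehicle, 2171 and 562 for trimebutine and alprostadil minus uninjured vehicle, 4175 for all wound groups, 5302 for the 4-group test, and 0 for alprostadil minus wound vehicle and for trimebutine minus alprostadil. The weights ran from 0.3 for wound alprostadil replicate 1 to 5.99 for uninjured vehicle replicate 2, so that few arrays carried the fit. In 100 splits of the 12 arrays into 4 groups of 3, with weights refitted, 11 splits gave as many genes in the 4-group test as the real one, the real one included, and the highest other gave 8623, so chance was not excluded for that test. Splits with weights were not run for the other counts.

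Of 45 list calls from camera in the first 4 comparisons, 0 held with an estimated correlation and 0 with fry in 1 direction. No gene named for these comparisons changed sign past the threshold under the alternatives run for single genes. Those leave out all probe sets, the other thresholds, the stricter filter and the fit without the 3 arrays of lowest median. For alprostadil minus wound vehicle, the macrophage median ranged from -0.325 to 1.566 when 1 array was left out, lowest without wound alprostadil replicate 1, and was -0.325 without the 3 arrays of lowest median and -0.023 with array weights. For trimebutine minus alprostadil it ranged from -2.016 to -0.010, with the test turned to higher at -0.010, which was without wound alprostadil replicate 1. The interferon list of alprostadil minus wound vehicle ranged from -0.129 to 0.232 and passed as lower at -0.129, without wound alprostadil replicate 3. That of trimebutine minus alprostadil was -0.010 without the 3 arrays of lowest median. The hypoxia list of trimebutine minus alprostadil ranged from -0.132 to 0.150 and passed as higher at 0.150, without wound trimebutine replicate 3.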

Other observations

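The splits for the planned comparisons were planned, and the comparison of all wound groups with its splits, and every other test of this part, were chosen after the results were seen. Those of macrophage RNA and of stress on the 32 genes replaced tests of these genes' spread within groups, which their choice had limited. That choice limits the replacements too. In all 9 wound arrays together against the 3 uninjured arrays, 32 genes passed in limma, 13 higher and 19 lower. Positional and patterning genes were among them: Hoxc9 (-0.88), Hoxc10 (-0.88) and Zic1 fell, and Tbx5 and Gata6 rose. Hoxb2, Hoxb3 and Hoxb4 lay higher by 0.38, 0.52 and 0.54 on all 9 wound arrays, and Hoxa5 and Hoxa6 lower by 0.61 and 0.55, without passing (adjusted p from 0.0893 to 0.22). Star, the cholesterol carrier of steroid synthesis, rose by 2.28 ± 0.36 and Tnfrsf11b (osteoprotegerin), a decoy receptor of RANKL, fell by 1.27 ± 0.18. The count of 32 was 0 without uninjured vehicle replicate 2 or the 3 arrays of lowest median, 4 without uninjured vehicle replicate 1, 6 without wound vehicle replicate 1 or wound trimebutine replicate 2, 8 without wound trimebutine replicate 3, 11 without wound vehicle replicate 3, 15 and 20 without wound alprostadil replicates 1 and 2, 58 without wound trimebutine replicate 1, 60 without uninjured vehicle replicate 3 and 76 without wound alprostadil replicate 3.

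Of 100 splits of the arrays into 3 against 9, 2 gave as many as 32 genes, the real one included, and the highest other gave 143, several times the real count, which points to a structure of the samples. That share lies under 0.05 but does not exclude chance, since it makes no allowance for the comparison having been chosen after the data were seen. The other 9 arrays of each split were regrouped at random, so that any differences between groups entered the spread. In the 4-group test 2 genes passed and 5 of 100 splits gave as many, with a highest other of 730, so chance was not excluded. For comparisons of 3 against 3 the 10 splits are too few for a share under 0.05. The real and highest other counts of genes were 6 and 994 for injury, 0 and 0 for trimebutine and 0 and 187 for alprostadil minus wound vehicle, 0 and 2 for trimebutine minus alprostadil, 26 and 0 for trimebutine minus uninjured vehicle, and 0 and 1 for alprostadil minus uninjured vehicle, with 2, 10, 10, 10, 1 and 10 splits as large. For lists by camera they were 14 and 20, 12 and 20, 7 and 19, and 12 and 18, with 4, 4, 8 and 4 splits as large. The split with 994 genes sets uninjured vehicle replicates 1 and 2 and wound vehicle replicate 3 against the other arrays, which points to a structure of the samples.

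A candidate explanation for the 32 genes is that skin of the wound groups was dissected from another part of the body. The 6 genes of the injury comparison were all among the 32, so it covers them too. Of 21 measured Hox genes, 7 put all 9 wound arrays on 1 side of the uninjured ones, 3 higher and 4 lower, where chance gives 0.91% and all tested genes gave 2.56%. These 7 include Hoxc9 and Hoxc10, already seen among the 32 genes. They also include neighbours of the same cluster, such as Hoxb2, Hoxb3 and Hoxb4, which may not vary independently. The chance share therefore does not measure how strongly the Hox genes speak for this explanation. A change of these genes by injury remains open, Hox and positional genes also differed between the wound groups given trimebutine and alprostadil (median 0.19, camera adjusted p = 0.0012, and 0.612 with an estimated correlation), and the skin site is not given in the sources used here. The 32 genes kept most of their difference without wound alprostadil replicate 1, the array with macrophage RNA. Of these, 15 passed without that array. The other 17 did not pass in that fit, which had 1 array fewer (highest adjusted p = 0.0851 in limma). Their median effect was 1.13 with the array (median SE 0.18) and 1.06 without it (median SE 0.16). The median ratio within these genes was 0.98 and the lowest 0.941. The 32 genes were chosen for differences large against their spread within groups, and the array is 1 of 9 wound arrays. The ratios could therefore hardly be low, and do not decide on macrophage RNA. The stress state of the cultures was examined only as far as the stress score measures it. With that score as a covariate 31 of the 32 genes passed, in a fit that gave 50 genes. Psd did not pass (adjusted p = 0.0582 in limma), but was lower by 0.50 ± 0.08 before and by 0.48 ± 0.09 after (ratio 0.98). Over the 32 genes the lowest ratio was 0.878. The score varied widely within groups, from -0.64 to 0.50 in uninjured vehicle. A gene that followed it would vary within groups too and was unlikely to be chosen, so this fit does not decide on stress.

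Collagen and endoplasmic reticulum stress scores correlated over the 12 arrays at Pearson r = -0.802 (permutation p = 0.00162) and Spearman rho = -0.741 (permutation p = 0.00773), adjusted over 3 relations to 0.00486 and 0.0232, with r = -0.746 without the 2 farthest arrays and -0.789 within groups. Stress and mitosis scores gave r = -0.520 (permutation p = 0.0835, adjusted 0.0835) and rho = -0.392 (permutation p = 0.211, adjusted 0.211), which did not pass, with r = -0.766 without the 2 farthest arrays and -0.457 within groups. Collagen and mitosis scores gave r = 0.686 (permutation p = 0.0143, adjusted 0.0214) and rho = 0.601 (permutation p = 0.0429, adjusted 0.0644). Here r was 0.675 within groups, and 0.375 without the 2 farthest arrays, so that the size of this relation depends on them. These lists were picked from 35 after the spread of the arrays was noticed, a choice that adjustment over 3 relations does not allow for.

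The wound vehicle and wound alprostadil arrays spread between higher collagen with low stress and the opposite. Uninjured vehicle arrays spread mainly in stress (-0.64, -0.50 and 0.50), with collagen scores of 0.43, 0.50 and 0.10. Wound trimebutine arrays had collagen scores of 0.31, 0.19 and 0.21, and replicate 1 was the highest of them in stress too (0.19 against -0.52 and -0.55). An exchange of labels between uninjured and wound vehicle replicate 3 is argued against, as 49 of 50 genes put the latter with the drug groups, where an exchange needs both out of place; this bound replaced, after the result was seen, one of 40 genes placing both as labelled, which was not met at 22. A wrong label among the wound groups remains open, since over genes wound vehicle replicate 3 correlated at 0.991 and 0.988 with wound trimebutine replicates 2 and 3 but at 0.955 and 0.945 with wound vehicle replicates 1 and 2, and wound alprostadil replicate 2 correlated with these last arrays at 0.991 and 0.988. A wrong label of a single array remains open too, as 22, 26 and 32 of 50 genes placed uninjured vehicle replicate 3, wound alprostadil replicate 3 and wound trimebutine replicate 1 as labelled, against 41 to 50 for the other arrays. Array quality, treatment and chance cannot be told apart for this axis, since groups held a share of 0.451 of the first component (permutation p = 0.151), and its r of -0.151 with the array median (95% interval -0.667 to 0.463) was judged void after it was seen, as normalisation makes the medians nearly equal (6.57 to 6.74).

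Wound alprostadil replicate 1 may hold leukocytes carried into culture: 15 of 16 measured macrophage markers, which restate the pattern noticed, stood at least 1 log2 unit above every other array, with Lyz2 at 12.84, Cd68 at 12.61 and Tyrobp at 11.88. All 16 lay above the array median on at least 3 arrays by the filter, 1 is also in another list, and Lyz2 reached 10.96 elsewhere. Of 31 keratinocyte, endothelial and Schwann cell markers 3 did so (9.7%), so most markers of these other cell types did not share the rise. This does not test a shift of the whole array, which normalisation would largely remove. An effect of alprostadil in all 3 cultures is argued against, since the score of the other arrays of the group lay at -0.571 (SE 0.396) relative to wound vehicle.

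The imprinted gene cluster between Dlk1 and Dio3 (43 measured members) had array scores of -0.90, -1.45 and -0.76 on the arrays of lowest median, which are replicate 1 of uninjured vehicle, wound alprostadil and wound trimebutine, and of 1.23 and 0.91 on wound trimebutine replicates 3 and 2, 0.78 on wound vehicle replicate 3 and 0.73 on wound alprostadil replicate 3. On the remaining arrays the scores were 0.04 and -0.13 (uninjured vehicle replicates 2 and 3), -0.16 and -0.30 (wound vehicle replicates 1 and 2) and 0.01 (wound alprostadil replicate 2). Over 139 other microRNA genes the 3 arrays of lowest median scored -0.23, -0.26 and -0.23, and the other 9 between -0.04 and 0.13.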
